A study of Mus musculus with 6 samples.

How the data were processed

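The data were expression profiles of mouse megakaryocytes, the cells that release platelets, grown from fetal liver cells with thrombopoietin, the hormone that drives their differentiation. Mature cells were isolated on a gradient of bovine serum albumin, and the mice had a mixed C57BL/6xSv129 background, per the labels. There were 6 arrays. The control group held 3 arrays, 2 from FOG1+/- and 1 from FOG1+/+ cultures, and the other 3 arrays came from cultures named FOG1-/- ki/ki in the labels and FOG1 ki/ki here. FOG1, encoded by Zfpm1, is a cofactor of the GATA transcription factors. RNA was amplified and labelled with NuGEN Ovation kits, per the labels' protocols. The labels call the samples biological replicates and do not say whether same-numbered cultures shared a litter or a day.

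The values deposited by the authors were array intensities on a linear scale, 1 per probe set, made with MAS5, per the submitters' processing notes, with no version given. The 2% trimmed mean of each deposited intensity column was 150, so the arrays had been scaled to one target. Replicates 1 and 2 of both groups were rounded to 1 decimal and replicate 3 of both groups was not. Scanner files were not used here. A scaled signal cannot show a change in total RNA per cell, and MAS5 values are noisy near background. The number of arrays limits the precision.

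Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several, and 9160 had none and were not control probe sets. The 64 control probe sets were left out of the tests, 51 of them with no symbol and 13 counted above with 1 symbol. The Entrez identifiers of 34754 probe sets matched the RefSeq table (assembly GRCm38.p6), and 0 symbols needed updating. That table served for names and for which genes neighbour each other, and the source of the values named no genome build, so no coordinates are given. Intensities were analysed as log2(signal + 16), which understates the change of dim genes. The lower 50% of probe sets by mean were left out, each gene was taken from its brightest probe set naming that gene alone, and 11260 genes were tested.

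FOG1 ki/ki was compared with control by limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 27 gene lists, the 24 with at least 5 genes tested were compared with all other genes by limma's camera, two-sided, with a preset correlation between genes of 0.01. Control probe set ratios were compared by an exact two-sided permutation test. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest. The groups, tests, gene lists, processing settings to vary and naming rule were set before the data were examined. The rule named Zfpm1, Gata1, Gata2, Itga2b and Gp6 always, up to 12 genes per direction with the largest changes among those past the test with non-overlapping groups, filled to 12 by the smallest unadjusted p, and up to 4 members of each list with the smallest unadjusted p.

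Both groups carry replicate numbers 1 to 3. Deviations from the group means of same-numbered arrays correlated across probe sets at 0.438, 0.648 and 0.597, while those of differently numbered arrays correlated at 0.0229 or lower. Deviations within a group sum to 0, so positive values for same numbers force lower ones for different numbers. The contrast is thus partly built in. The positive correlations of same-numbered arrays were read as pairing before the fits were compared. The tests without the pairing remained the main ones, as planned, and values with the replicate number as a block are given beside results that it changes.

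The fits were tested on simulated data, 20 sets of 11260 genes with 200 changed genes each, in 2 versions that differ in the variances given to the genes. With each gene's posterior variance taken as true, the fit without the block recovered 8.6% of log2 changes of 1 and 63.4% of log2 changes of 2, with 0.139% false calls. The blocked fit recovered 77.5% and 99.8%, but 9.63% of its calls were false, above the nominal rate. The second version was made after that result was seen and drew the variances from limma's own fitted prior, which is the case that favours limma. There the fit without the block recovered 5.3% and 49.6% with 0.723% false calls, and the blocked fit 37.9% and 91.8% with 4.77% false calls. Counts from the blocked fit of the real arrays can therefore hold more false calls than the threshold states. Camera found 20 of 20 lists of 30 genes shifted by 0.5 in both versions and both fits. It passed 0 of 20 unshifted lists in the first version and 1 of 20 in the second, counted at an unadjusted p under 0.05. Simulated list members were drawn at random and varied independently apart from the pair effects. The self-test therefore does not cover lists whose genes vary together, such as the fibroblast list with an estimated correlation of 0.88.

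The settings varied were other pseudocounts, quantile normalization, median centring, other filters on dim probe sets, the block, array weights, other variance models, other ways to treat a gene's probe sets, other thresholds, an estimated correlation in camera, fry, and leaving out each array or each number. Blocked versions of several of these were added after the data were seen.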

Results

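Expression was measured on 6 arrays of mouse fetal liver megakaryocytes, 3 from control and 3 from FOG1 ki/ki cultures. The control group pooled 2 FOG1+/- arrays, replicates 1 and 2, with 1 FOG1+/+ array, replicate 3. The comparison asks how the transcripts of megakaryocytes differ when the only FOG1 comes from the knocked-in allele. The median signal ranged from 5.93 in FOG1 ki/ki replicate 3 to 12.3 in FOG1 ki/ki replicate 1.

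Zfpm1, the gene that encodes FOG1, was measured at a similar level in both groups. Its mean signal was 810 ± 357 in controls and 874 ± 397 in FOG1 ki/ki (SD, n = 3 each), a log2 difference of 0.11 (SE 0.44, limma adjusted p = 0.999). The pair differences were 0.15, 0.01 and 0.16. A second, dimmer Zfpm1 probe set differed by 0.07. The knocked-in allele can still be transcribed, so these levels do not check the genotype labels. Gata1, the main GATA factor of megakaryocytes, differed by -0.13 (adjusted p = 0.999), and Itga2b, a subunit of the platelet fibrinogen receptor, by -0.07 (adjusted p = 0.999).

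The log2 ratio of 3' to 5' signal was 0.67 ± 0.32 in controls and 0.74 ± 0.50 in FOG1 ki/ki for Gapdh (SD, n = 3 each, exact two-sided permutation p = 1) and 0.85 ± 0.29 against 0.99 ± 0.51 for beta-actin (exact two-sided permutation p = 0.8), where 0.1 is the smallest p that 3 against 3 arrays allow, so no difference in RNA quality could have passed. The ratios themselves were highest in FOG1 ki/ki replicate 3, at 2.38 for Gapdh and 2.76 for beta-actin, against 1.86 and 1.93 in control replicate 3. The arrays also differed by replicate number. A control probe set for the mouse B2 repeat read 2359 and 2420 on the replicate 1 arrays and between 51.3 and 93.2 on the other 4. Another B2 control probe set went the other way, with 467 and 621 on the replicate 1 arrays and 2710 to 3707 on the rest. A BioC spike-in control probe set read 219 and 235 on the replicate 1 arrays and 754 to 974 on the rest. The cause was not tested.

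Between FOG1 ki/ki and control, 11 genes rose and 6 fell among 11260 tested. Gbp6, a member of the interferon-inducible guanylate-binding protein family, rose from a mean signal of 62.3 to 973 (log2 difference 3.72, SE 0.34, adjusted p = 0.0239). Bcl2, which protects cells from apoptosis, rose from 280 to 931 (log2 difference 1.67, adjusted p = 0.047, and 0.0581 with a pseudocount of 1). Apcdd1, an inhibitor of Wnt signalling, fell from 663 to 11.7 (log2 difference -4.60, SE 0.29, adjusted p = 0.00403). Bmp2, a bone morphogenetic protein, fell from 258 to 18 (log2 difference -3.05, adjusted p = 0.0239). Both ended near background, so the pseudocount sets the size of these differences. Apcdd1 was at -5.72 with a pseudocount of 1 and at -3.24 with one of 64, and Bmp2 at -3.94 and -1.97.

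The other genes that rose were Gm20161 (log2 difference 3.04), the sodium channel gene Scn10a (2.82), Qprt of NAD synthesis (2.68), Lim2 (2.63), Car8 (2.54), Crisp3 (2.39), Nrip3 (2.32), Syde2 (1.98) and Tbc1d24 (1.54). Mean control signals of Gm20161, Scn10a, Qprt, Lim2, Car8, Crisp3 and Nrip3 lay between 4.22 and 19.8, near background, so the pseudocount sets the size of their differences too. The other genes that fell were Pdlim1 (log2 difference -2.74), the synaptotagmin Syt13 (-2.16), Sh3bgrl2 (-1.84) and Mmd (-1.65). The groups did not overlap for any of the 17, so all necessarily changed in the same direction in all 3 pairs. With a pseudocount of 1 only Gbp6, Scn10a, Qprt, Crisp3, Nrip3, Apcdd1, Pdlim1 and Syt13 still passed. Gm20161, Syde2, Bmp2, Sh3bgrl2 and Mmd then had adjusted p = 0.0521, Bcl2 and Tbc1d24 0.0581, Lim2 0.12 and Car8 0.123. The next genes by unadjusted p did not pass. Il10 had a log2 difference of 2.16 (adjusted p = 0.0636) and a mean control signal of 6.13, near background. Serpini1 (-2.32), Ddit4l (-1.90), Fas (-1.67), A930003A15Rik (-2.15), Pxdc1 (-3.17) and Ndnf (-1.96) had adjusted p between 0.0575 and 0.0965.

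With the replicate block, 47 genes rose and 47 fell, and these 94 included all 17. Il10, Serpini1, Ddit4l, Fas, Pxdc1 and Ndnf passed then, and A930003A15Rik did not (adjusted p = 0.0522). On simulated data, false calls made up 4.77% or 9.63% of blocked calls, depending on how variances were simulated. Leaving out any 1 array lowered the unblocked count to 1 or 2 genes, and leaving out a pair lowered it to 0.

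**Figure D1:**
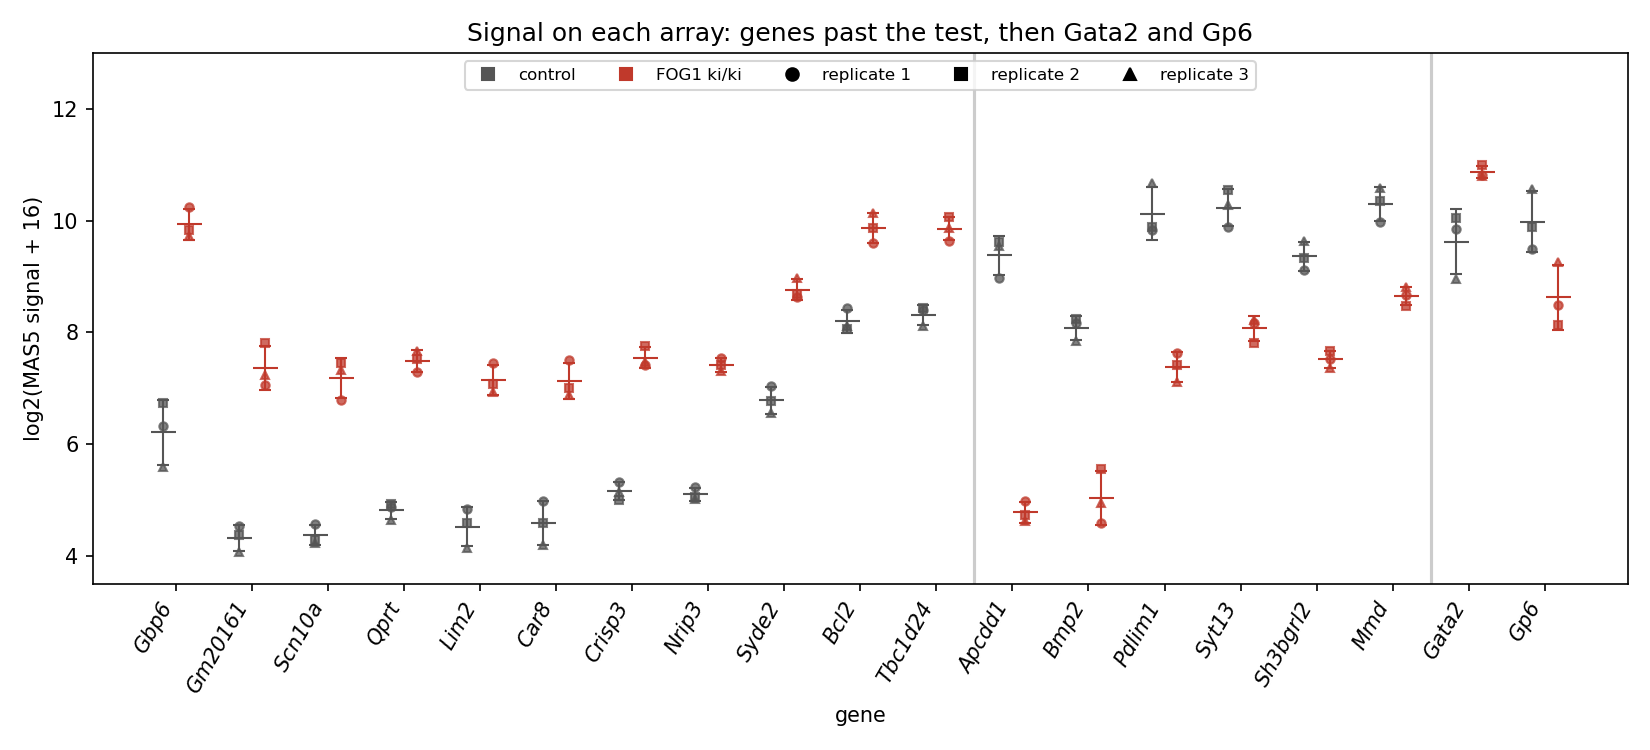
Signal of the 17 genes past the test, then Gata2 and Gp6, as log2(MAS5 signal + 16) on each array; bars are means and SDs of 3 arrays, and symbols mark the replicate number. The groups do not overlap for any gene shown, and Gata2 and Gp6 did not pass the test without the block.

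Camera passed 9 of 24 gene lists, and other splits of the 6 arrays passed 5 to 13, so its p values below do not set the groups apart from other differences between arrays. Platelet surface receptors lay lower in FOG1 ki/ki, with 29 of 32 tested members below control and a median log2 difference of -0.32. Gp6, the platelet collagen receptor, had a mean signal of 1043 in controls and 403 in FOG1 ki/ki (log2 difference -1.35, SE 0.37, adjusted p = 0.356), and with the replicate block it fell (adjusted p = 0.0342). Esam, a junctional adhesion molecule, also fell with the block (log2 difference -1.89, blocked adjusted p = 0.0342). The ADP receptor P2ry12 had a log2 difference of -1.44 and the adhesion receptor Cd226 one of -1.99, while Tspan33 stood 2.18 above control. P2ry12 was dim, with mean signals of 41.7 in controls and 4.90 in FOG1 ki/ki, so the pseudocount sets the size of its difference. Camera's adjusted p for the list was 7.11e-09, and adjusted p = 0.755 with an estimated correlation. With limma 0 members passed over all genes without the block and 2 fell with it. Adjusted over the list alone 5 fell and 1 rose, or 16 fell and 1 rose with the block. The list shares 2 tested genes with the alpha granule list and 3 with the collagen receptor list, and its median was -0.21 without control replicate 3.

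Other platelet lists also lay lower. Of alpha granule genes, 21 of 27 were below control (median -0.21, camera adjusted p = 0.000176, adjusted p = 0.755 with an estimated correlation). The median was -0.0964 without FOG1 ki/ki replicate 1 and -0.12 without control replicate 2. Coagulation factor F5 had a log2 difference of -2.16, thrombospondin Thbs1 -1.38, F13a1 -1.50 and Pdgfb -0.88. The abundant granule genes Pf4 (-0.0028), Ppbp (-0.05) and Vwf (-0.19), named after the values were seen, were close to control. Adjusted over the list alone 1 alpha granule gene fell, F5, and 8 fell with the block, against 0 over all genes in both fits. Of collagen receptor signalling genes, 18 of 29 were below control (median -0.10, adjusted p = 0.0264, adjusted p = 0.781 with an estimated correlation), with Tec at -1.12, Grap2 at -1.53 and Clec1b at -0.36. Of these, 1 fell with the block over all genes and over the list alone, Gp6. Of proplatelet cytoskeleton genes, 24 of 30 were below control (median -0.05, adjusted p = 0.0319, adjusted p = 0.757 with an estimated correlation), with the megakaryocyte tubulin Tubb1 at -1.01, Myl9 at -1.78, Tmod3 at -0.71 and Actn1 at -0.81. Adjusted over the list alone 1 proplatelet gene fell, Tubb1, and 3 with the block, against 0 over all genes. The collagen and proplatelet shifts no longer passed without control replicate 3 (adjusted p = 0.673 and 0.396), FOG1 ki/ki replicate 1 (0.222 and 0.295), FOG1 ki/ki replicate 2 (0.183 and 0.109) or both arrays numbered 2 (0.117 and 0.252), and the proplatelet shift also without control replicate 2 (0.224). Without FOG1 ki/ki replicate 1 both medians turned positive, to 0.0312 and 0.0189, and the collagen median was -0.00313 without control replicate 3. Neither passed with no filter on dim probe sets (0.058 and 0.0835). Without control replicate 1 or FOG1 ki/ki replicate 3 both passed with lower medians, -0.26 in either case for the collagen list and -0.15 in either case for the proplatelet list.

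Genes of cell division lay higher. Of mitosis genes 29 of 30 were above control (median 0.32, camera adjusted p = 0.000176, adjusted p = 0.757 with an estimated correlation), and of DNA replication genes 30 of 31 (median 0.28, adjusted p = 0.000606, adjusted p = 0.757 with an estimated correlation). The proliferation marker Mki67 had a log2 difference of 0.78, Ccnb2 0.46, Cdc20 0.32 and Kif11 0.60, and Mcm7 0.33, E2f1 0.53, Uhrf1 0.32 and Mcm3 0.43. With limma 0 members of either list passed over all genes or adjusted over the list alone, with or without the block. At an unadjusted p under 0.05 there were 1 mitosis and 0 DNA replication genes, or 10 and 5 with the block. Over all 11260 genes tested there were 753, or 2076 with the block. The mitosis shift was -0.0044 and the DNA replication shift 0.04 without control replicate 3, the FOG1+/+ array (adjusted p = 0.573 and 0.609). With both arrays numbered 3 left out, which keeps the other pairs whole, the shifts were 0.171 and 0.173 (camera adjusted p = 0.0050 and 0.0038). They were 0.49 and 0.46 without control replicate 1, and the DNA replication shift was 0.44 without FOG1 ki/ki replicate 3.

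Mast cell and basophil genes lay higher, with 18 of 20 above control and a median of 0.74 (camera adjusted p = 0.000176, adjusted p = 0.755 with an estimated correlation). The median was 0.44 without control replicate 3, 1.24 without FOG1 ki/ki replicate 3 and 0.43 with no filter on dim probe sets. Ms4a2, a chain of the IgE receptor, had a mean signal of 59.4 in controls and 486 in FOG1 ki/ki (log2 difference 2.77, adjusted p = 0.255), and it rose with the block (adjusted p = 0.00902). Gata2, a GATA factor of progenitors and mast cells, had 813 and 1860 (log2 difference 1.25, adjusted p = 0.242, blocked adjusted p = 0.0584). A second Gata2 probe set differed by 1.60. Gzmb had a log2 difference of 3.06 and Mcpt1 one of 1.36. Adjusted over the list alone 2 rose, Gata2 and Ms4a2, and 5 with the block, against 0 and 1 over all genes. Fcer1a and Gzmb, singled out after their values were seen, read 93.1 and 5.96 in the FOG1+/+ control but 3912 and 1785 in FOG1 ki/ki replicate 3, while the FOG1+/- controls had 1891 and 2168 for Fcer1a and 327 and 189 for Gzmb. For Cpa3 (68.2 and 170), Hdc (17.8 and 19.6) and Ms4a2 (13.3 and 189) the replicate 3 arrays, control and FOG1 ki/ki, each read below the other arrays of their group. The list median was 0.60, 0.57 and 0.44 in pairs 1, 2 and 3.

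Monocyte and macrophage genes lay lower in 33 of 34 cases (median -0.72, camera adjusted p = 8.37e-09, adjusted p = 0.757 with an estimated correlation), with Trem2 at -1.27, Cd68 at -1.26, Cd5l at -0.92 and Adgre1 at -1.31. The list medians were -1.49, -0.42 and -0.25 in pairs 1, 2 and 3. Over all pairs the median was -0.42 without control replicate 2, -0.39 without FOG1 ki/ki replicate 1 and -1.16 without FOG1 ki/ki replicate 2. Fibroblast and stromal genes lay lower in 23 of 23 cases (median -0.74, adjusted p = 0.00266, adjusted p = 0.781 with an estimated correlation), with Postn at -1.26, Vim at -0.31, Col6a3 at -0.71 and Lum at -0.46, and their median turned to 0.23 without control replicate 2 (adjusted p = 0.801). The shift also no longer passed without FOG1 ki/ki replicate 3 (adjusted p = 0.509) or both arrays numbered 2 (0.0774), or in the brightest 25% of probe sets alone (0.0793). With the block and without both arrays numbered 2, the fibroblast list passed (median -0.31, camera adjusted p = 0.0086). It also passed there when the groups of 1 remaining pair were swapped (median -0.24, camera adjusted p = 0.0171). The median was -1.84 without control replicate 3 and -1.36 without FOG1 ki/ki replicate 2. With limma 0 members of either list passed over all genes or adjusted over the list alone, in either fit. At an unadjusted p under 0.05 there were 2 macrophage and 0 fibroblast genes, or 16 and 9 with the block, against 753 or 2076 of all 11260 genes. Camera with the block passed the same 9 lists.

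**Figure D2:**
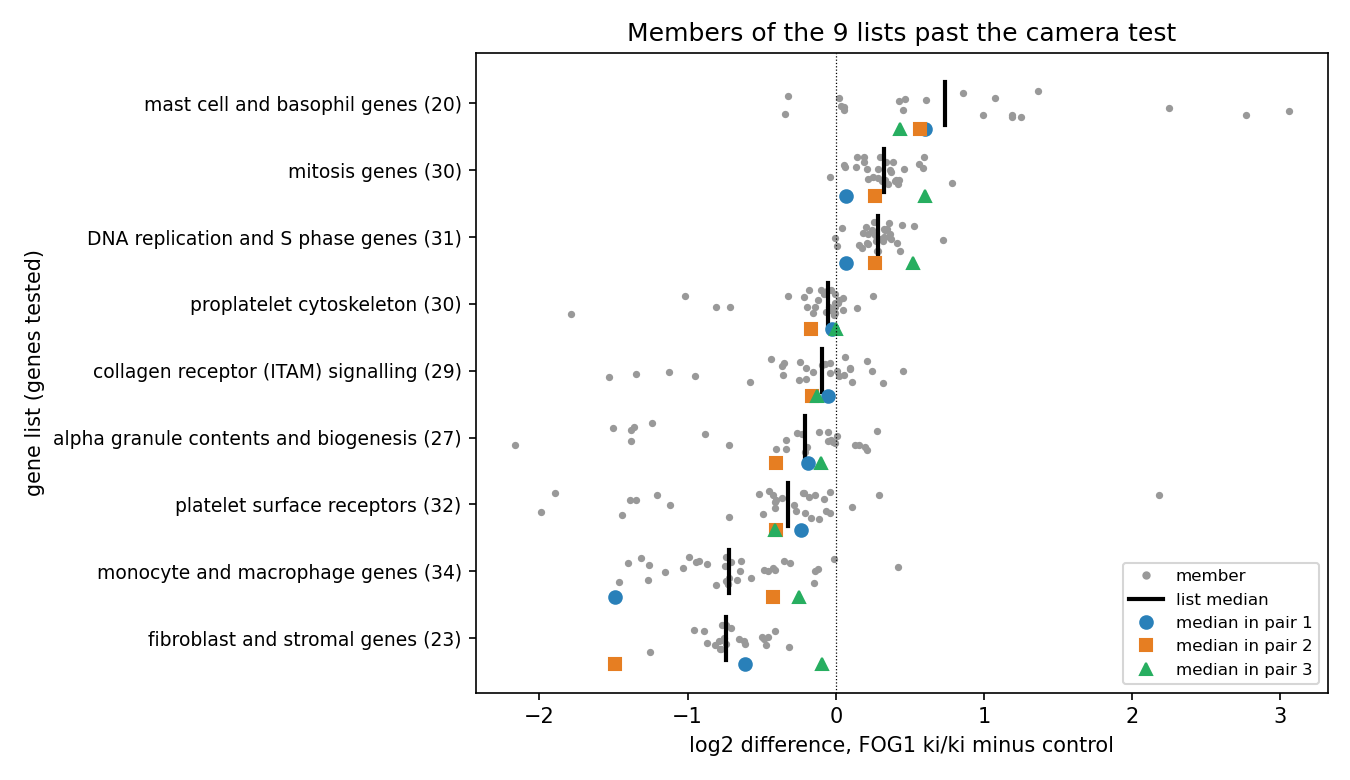
Log2 difference, FOG1 ki/ki minus control, of each tested member of the 9 lists past the camera test; black lines are list medians and coloured symbols the median in each replicate pair. The macrophage medians run from -1.49 in pair 1 to -0.25 in pair 3, and the fibroblast list is lowest in pair 2 at -1.49.

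The other 15 lists tested did not pass, with camera adjusted p from 0.0824 to 0.8. Among megakaryocyte and erythroid transcription factors (adjusted p = 0.0824), Klf1, a factor of red cell precursors, had a log2 difference of 1.86 from a dim mean control signal of 22.3. Gata2 differed by 1.25, Lmo2 by 0.35 and Meis1 by 0.50. The ribosomal protein list had the same p, with Rpl14 at 0.38, Rps9 at 0.13, Rpl8 at 0.14 and Rpl19 at 0.12. The neutrophil list (0.162) held Cebpa at -1.10, Mgst1 at -0.96, Ltb4r1 at -0.40 and Ms4a3 at 0.73. The heat shock and immediate early list (0.207) held Gadd45b at -2.40, which fell with the block (adjusted p = 0.048), Gadd45a at -1.65, Zfp36 at -0.68 and Hsp90aa1 at 0.18. NuRD subunits (0.219), the complex that FOG1 binds, held Cdk2ap1 at 0.19, Rbbp7 at 0.20, Mbd2 at -0.15 and Mta1 at 0.22. The G1 list (0.229) held Ccnd1 at 0.88, Myc at 0.75, E2f2 at 0.63 and Mdm2 at -0.39. The lymphoid list (0.27) held Nkg7 at 2.06, Il7r at -1.24, Blnk at -1.03 and Ebf1 at -1.004. The respiratory chain list (0.365) held Cox7c at 0.83, Sdhb at 0.30, Ndufb3 at 0.20 and Cox6c at 0.13.

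The endothelial list (0.469) held Tek, a receptor of angiopoietins, which rose with the block (log2 difference 1.77, blocked adjusted p = 0.0437). Its other named members were Esam at -1.89, Clec4g at -1.21 and Cd34 at -0.70. The stem and progenitor list (0.8) held Nrgn, which fell with the block (log2 difference -1.58, blocked adjusted p = 0.00902), with Tek at 1.77, Gata2 at 1.25 and Mecom at 2.13. The dense granule list (0.497) held Slc18a2 at 1.13, Abcc4 at -0.78, Slc35d3 at -0.92 and Lyst at -0.77. The erythroid list (0.497) held Tspan33 at 2.18, Klf1 at 1.86, Hbb-b2 at -0.63 and Fech at -0.46. The eicosanoid list (0.502) held Alox12, the platelet lipoxygenase, at -1.94, Alox5 at 0.47, Hpgd at -0.50 and Ltc4s at 0.44. The cholesterol list (0.753) held Idi1 at -0.24, Insig1 at 0.18, Hsd17b7 at 0.16 and Msmo1 at -0.11, and the interferon list (0.8) Ifit1 at -2.01, Oas3 at 1.06, Ifit2 at -0.82 and Ifit3 at -0.93. The test ran against the sign of the median for the dense granule, interferon and stem lists and against the sign of the mean for the erythroid and stem lists.

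With limma 0 of the 563 list genes tested passed over all genes, and 6 passed with the block, 4 lower and 2 higher. Without the block 55 of the 563 had an unadjusted p under 0.05, against 753 of all 11260 genes. The eosinophil, hepatocyte and sex-specific lists had 4 genes tested each, too few for the test. Siglecf was at 0.87, Prg3 at -0.05, Prg2 at -0.09 and Epx at 0.02. Prg3, Prg2 and Epx read far lower on both replicate 3 arrays than on the other arrays, which these differences do not show. Afp was at -0.50, Apoc2 at -0.73, Rbp4 at -0.47 and Apoa2 at 0.21. Of the sex-specific genes, the Y-linked Eif2s3y read 2.5 in control replicate 1 and 1147 in FOG1 ki/ki replicate 1, and Xist read 807 and 2.4, so the replicate 1 cultures differed in sex. Over all arrays Xist differed by -1.71, Eif2s3y by 2.03, Kdm5d by 1.16 and Uty by 0.91.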

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

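The tests of the list count, of sex, of the FOG1+/+ control and of admixed mast cells and macrophages were chosen after their results had been seen in part. The thresholds for the macrophage shares were written after the values were known.

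Probe sets without a single gene name were not part of the comparisons of genes and entered only where each probe set was tested singly, and a signal appeared there above the control level. Of 2513 tested with the replicate block, 9 were higher in FOG1 ki/ki, by log2 differences of 1.13 to 4.38, and 9 were lower. Groups of 3 arrays were not searched for single outlying arrays.

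The count of changed genes was set against other splits of the arrays. The real split gave 17 genes, and only 1 of the 10 splits, the real one, gave as many. The highest other gave 16, for controls 1 and 2 with FOG1 ki/ki 2 against the rest, a split that parts 1 pair. Counted at an unadjusted p under 0.05, the real split gave 753 genes. Splits with 824, 1259 (the split with 16 calls) and 1517 genes exceeded it, and the remaining ones gave 17 to 641. With the replicate block the real split gave 94, as many as only 1 of the 4 splits that part all 3 pairs, itself, and the highest other gave 0. Both sets of splits are too few for a share under 0.05. For camera 5 of the 10 splits, the real one included, passed as many as the 9 lists, and the highest other passed 13, so the number of shifted lists does not set the real groups apart. The difference in sex in pair 1 and the FOG1+/+ control in pair 3 cannot act where that pair is left out. The blocked fit called 207 genes in pairs 2 and 3 alone and 359 in pairs 1 and 2 alone, against 0 in the other split that parts both pairs. In that other split, and in the other splits that part all 3 pairs, a difference shared by the pairs counts as spread, which lowers the calls. Leaving out a pair also raised the count above 94, and fits this small were not simulated. Of the 94 genes, 82 were called again without pair 1 and 94 without pair 3. Their median absolute differences were 1.68, 1.78 and 1.97 in pairs 1, 2 and 3. The 94 were picked with all pairs, which favours such agreement. Still, a cause confined to 1 pair cannot act in the others, so these values argue against either as the whole source of the 94 genes. A part in the differences of its own pair stays open. Strain DNA linked to Zfpm1 would place the 94 called genes nearby, and 0% of the 92 with a position lay within 20 Mb of it (upper exact bound 3.93%). The altered FOG1 is the biological explanation that the design names, and it was not tested apart from other differences between the cultures.

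The higher level of mast cell and basophil genes may reflect mast cells mixed into the FOG1 ki/ki cultures. The 5 abundant mast cell transcripts that could be tested (Cpa3, Cma1, Hdc, Fcer1a and Ms4a2) had median differences of at least 0.73 in pairs 1 and 2 and of 1.14 in pair 3, above the other members' 0.34, 0.39 and 0.43. The other 4 of the 9 transcripts chosen, Tpsb2, Tpsab1, Mcpt4 and Mrgprb1, read at most 16.3 on any array. No array of mast cells was available to show what these probe sets read there, so the low readings do not decide about mature mast cells. Of the tested 5, 2 had helped raise the question. Mast cells and a change within megakaryocytes therefore cannot be told apart here. Mature megakaryocytes were isolated on a gradient, and which other cells it left was not measured. The eosinophil gene Prg2 read 1777, 1224 and 16.2 in control replicates 1, 2 and 3, and 1060, 1396 and 23.1 in FOG1 ki/ki. Epx read 205, 211 and 1.34 in controls, and 174, 220 and 4.15 in FOG1 ki/ki. Signals of these eosinophil genes thus differed by replicate number in both groups.

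The lower level of monocyte and macrophage genes may reflect fewer macrophages in the FOG1 ki/ki cultures. At least 91.2% of members were lower in pairs 1 and 2, which is consistent with that, though the 90% bound was set with the values known. In pair 3 it was 67.6% (Wilson interval 50.8% to 80.9%), short of 90% but with an upper bound above 75%, so for this pair fewer macrophages stay undecided. These intervals treat members as independent. The difference in sex in pair 1 stays open as a source of the larger shift there. Pairs 2 and 3 matched in sex, with Eif2s3y at 841 to 1186 and Xist at most 4.6. Sex therefore cannot lower the list in them. In pairs 2 and 3 alone the list median was -0.35 (bootstrap interval -0.40 to -0.24) and the list passed, but it also passed in the other split of these 4 arrays that parts both pairs (median -0.0763, camera adjusted p = 0.0320). Whether the lower level in pairs 2 and 3 exceeds other differences between cultures is therefore not settled. A change of macrophage genes within other cells was not tested.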

How the results depend on the processing

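Alternatives that combine the block with another choice, or leave out a pair under it, were chosen after seeing the data; the rest were planned. The 17 changed genes (11 higher, 6 lower) became 8 (5 and 3) with a pseudocount of 1, 1 (0 and 1) with no filter on dim probe sets, 3 (1 and 2) in the brightest 25% of probe sets, 41 (23 and 18) with array weights and 31 (18 and 13) at a threshold of 0.10, and 3 instead of 6 were lower with the mean of a gene's probe sets. Without the filter more genes are tested, and a looser threshold passes more by construction; for the others the cause was not tested. With each probe set tested singly, 15 probe sets passed, or 118 with the block (55 and 63), of which 18 had no single gene name; these count probe sets and not genes. With the replicate block there were 94 genes (47 and 47), with the block and quantile normalization 97 (44 and 53), and with pair 1, 2 or 3 left out of it 207 (84 and 123), 128 (64 and 64) and 359 (118 and 241). Leaving out 1 array or 1 number gave 0 to 2 genes, 0 to 1 higher and 0 to 1 lower, where fewer arrays remain. At 0 genes, limma gave 472 to 694 at an unadjusted p under 0.05, against 753 with all arrays. Under the other unblocked settings the count lay between 12 and 19. The 9 shifted lists became 0 with camera's estimated correlation, with or without the block, which allows for genes that vary together. Fry, which tests a list against no change and not against other genes, passed 0 lists, and 1 with the block, the mast cell list (adjusted p = 0.0229). Leaving out arrays gave 7 to 11. The replicate block changed no list call, and among the named genes only those whose blocked result is stated. Zfpm1 ranged from -0.28 to 0.48 over the arrays left out, -0.28 without control replicate 1 and -0.21 without FOG1 ki/ki replicate 3. The fibroblast list ranged from -1.84 to 0.23, turning positive without control replicate 2 (adjusted p = 0.801), the mitosis list from -0.00442 to 0.49, the collagen list from -0.26 to 0.0312 and the proplatelet list from -0.15 to 0.0189. The proplatelet median was also 0.00133 without replicate 2, with and without the block. Other values that turned sign lay near 0 or rested on single arrays; their ranges over the arrays left out were Apoa2 -0.0146 to 0.45, Col1a1 -2.01 to 0.60, Epx -1.21 to 1.15, Hdc -0.36 to 1.45, Id1 -0.0414 to 1.06, Itga2b -0.33 to 0.13, Msmo1 -0.21 to 0.010, Pf4 -0.0875 to 0.0793, Ppbp -0.17 to 0.0677, Prg2 -1.93 to 1.57, Prg3 -0.92 to 0.80, Rbp4 -0.85 to 0.13, Smad7 -0.25 to 1.39, Uty -0.0459 to 1.53 and Xist -2.74 to 0.17. Epx was -0.0228 with a pseudocount of 64, Pf4 0.0110 with median centring, Prg3 0.15 and Prg2 0.00705 with array weights, and Msmo1 0.0526 and Rps9 -0.11 with the mean of a gene's probe sets; none of these passed a test, and the cause was not tested. Signals near background limit the dim genes most: on every array over 50% of probe sets lay below the pseudocount of 16.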

Other observations

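The genes named below were chosen after their values were seen, except the BMP target genes, which were chosen before theirs were. Sytl4, an effector of the granule-docking protein Rab27, fell with the replicate block (log2 difference -2.07, blocked adjusted p = 0.0144), while Sytl2 (2.35, blocked adjusted p = 0.0296) and Rph3al (1.91, blocked adjusted p = 0.0202) rose with it. None of these passed without the block (adjusted p = 0.223, 0.0912 and 0.341). Sytl1 (0.15) and Unc13d (0.34), also Rab27 effectors, did not pass in either fit. Cd28, a T cell costimulatory receptor, fell with the block in all 3 pairs (log2 difference -2.77, blocked adjusted p = 0.00902, unblocked adjusted p = 0.223).

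Hjv, a BMP co-receptor, fell with the block (log2 difference -3.11, blocked adjusted p = 0.0125, unblocked 0.0988), as did Pmepa1 (-1.74, blocked adjusted p = 0.0295, unblocked 0.806), and Crim1 rose (1.46, blocked adjusted p = 0.0492, unblocked 0.281). The hypothesis that BMP signalling was lower predicted that the tested target genes would lie below -0.2 in each pair. Their medians over 6 genes (Id1, Id2, Id3, Smad7, Bambi and Atoh8) were -0.57, -0.33 and -0.0726, so pair 3 missed the bound and the test did not decide. Bambi (-1.07), Atoh8 (-1.04) and Id3 (-0.72) were lower, and Id1 (0.50), Id2 (0.78) and Smad7 (0.79) higher, with no adjusted p under 0.05 in either fit.

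The mast cell transcripts Hdc (0.45), Cma1 (0.86), Cpa3 (1.08) and Fcer1a (2.25), the macrophage transcripts C1qb (-0.74) and Csf1r (-0.74) and the collagen Col1a1 (-0.76) had these log2 differences, and none passed in either fit. Among the 94 genes called with the block, of which 92 had a position, 3 were placed on the X chromosome and 0 on the Y chromosome. The groups did not overlap for 712 genes higher and 555 lower in FOG1 ki/ki, 11.3% of those tested. Chance gives 10% if all arrays are exchangeable, but same-numbered arrays vary together, and the other 3 splits that part all pairs gave 2.09% to 3.68%. Each of these swaps the groups of 1 pair, so a difference shared by the pairs counts as spread and lowers the share. They therefore do not give the chance rate for the 11.3%. In the real grouping the sign agreed in all 3 pairs for 44.2%, where chance gives 25% on average. Genes vary together, so a single grouping can depart from that average by chance, and its spread was not measured.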
